A study of Homo sapiens with 12 samples.

How the data were processed

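KYSE150 cells, an established line of oesophageal squamous cell carcinoma, were transfected with a small interfering RNA (siRNA) against ANLN (siANLN) or with a control siRNA (siNC), and RNA was taken 24 h or 48 h later. ANLN encodes anillin, an actin-binding scaffold protein of the contractile ring in dividing cells. Each of the 4 groups had 3 libraries, 12 in all. Total RNA was extracted with Trizol, and poly(A) libraries were sequenced as paired reads on an Illumina HiSeq Xten, per the labels' protocols. The sequences of the siRNAs, the strand setting of the library kit and the strand setting of the counting were not given in the sources used here.

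The authors trimmed reads with cutadapt 1.18, aligned them with STAR 2.7.3a to GRCh38 and counted them per gene with featureCounts, per the submitters' processing notes, which also name DESeq2 1.44.0. The deposited tables hold, for each library, whole-number read counts per gene and FPKM values, which scale the fragments of a gene by its length and by the library total. There is 1 pair of tables for 24 h and another for 48 h. Every count below comes from the deposited counts, and the authors' deposited FPKM values were used only in an alternative test. The 24 h table listed 58735 gene IDs, all of which are in GENCODE release 29. The 48 h table held 38561 lines for 38318 gene IDs. Of these, 35484 are in GENCODE release 29, and 10844 had no symbol in the file. There 202 IDs were listed more than once, with identical values each time, and were kept once. At 24 h, 27 symbols had been stored in the file as dates, so symbols were taken from the annotation by gene ID.

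The tables of the 2 times were not made alike. Dividing counts by FPKM and the library total gave a whole gene length, to within 0.01, for 100.0% of genes at 48 h and for 0.0% at 24 h. The 24 h table lists 15 mitochondrially encoded genes, and 0 are listed at 48 h. Between 3.72% and 3.89% of the 24 h counts, and between 1.28% and 1.3% of the 48 h counts, lay in IDs absent from the other table. In the controls 4416 genes tested for a difference between the times had levels over 4-fold apart, 1102 of them over 100-fold, and why levels differed was not tested. Each time was tested within its own table, and the difference between the times was tested as a difference of the changes, over IDs in both tables. Time point and table processing cannot be separated.

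Counts were normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit) in R 4.3.3, over genes kept by filterByExpr. The fit of each time used its 6 libraries, with no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The adjusted p-values of single genes are from this test unless another tool is named. Levels are given as CPM (counts scaled to a common library size, with TMM factors), mean ± SD over 3 libraries. Control levels of single genes compared between the times are on a separate scaling and differ slightly from these. FOS in siNC at 48 h, for example, is 131 CPM there and 128 CPM elsewhere. Fold changes are on the log2 scale, siANLN over siNC, with their standard errors (SE). The difference between the times was the contrast of both changes in a model with 1 mean per group over all 12 libraries.

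Gene lists (26) were fixed before the data were examined. They cover cytokinesis, the cell cycle, RNA polymerase II and its factors, squamous and epithelial state, stress and innate responses, metabolism, RNA quality and other cell types. Lists with at least 2 genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move in 1 direction on balance without comparing them with other genes, were run beside it. Members were counted as changed by their adjusted p over all genes tested and, separately, adjusted over the list alone.

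Genes named in the text follow a rule fixed before the data were examined. It takes ANLN. At each time it takes the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between the siANLN and siNC libraries. From each called list it takes the 4 members with the smallest adjusted p in the direction of the list, and up to 2 members of every other list. It also takes the 8 genes with the smallest p for the difference between the times. Genes named outside the rule are said to be so, and 1 gene that the rule takes is not reported here. Coordinates are those of GENCODE release 29 on GRCh38, counted from 1.

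Total counts were 17083835, 17921808 and 15520365 in the siNC libraries and 14891932, 16575754 and 15456996 in the siANLN libraries at 24 h. At 48 h they were 11951942, 12113679 and 11805488 in siNC and 12448411, 11939862 and 12410129 in siANLN. Common biological coefficients of variation were 0.039 at 24 h and 0.02 at 48 h. Every pair of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 2.48 to 2.72 at 24 h and 1.27 to 1.49 at 48 h. No pair thus looked like 1 library sequenced again, and n stayed at 3. This excess does not tell separate transfections from separate preparations of 1 culture, so independence of the replicates rests on the labels.

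The gene test, the list test and the word search were first tested on simulated data. Of 50 simulated genes changed 2-fold, the test called 44 at 24 h (14484 genes run), 40 at 48 h (16786 genes run) and 26 for the difference between the times (17392 genes run). Of 50 changed 4-fold it called 46, 49 and 34. Among unchanged simulated genes it called 10, 9 and 2. The list that had been shifted was called in each of the 3 comparisons, with 3, 1 and 1 lists called in all. A 7-base word planted in the 3′ untranslated regions (3′ UTRs) ranked 1 in a search of 11873 genes.

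Alternatives chosen before the data were examined were DESeq2 size factors or library size alone in place of TMM, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, limma-voom, a fit on all 12 libraries, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter on mean FPKM of 0.5 or none, and stricter thresholds. Alternatives chosen after seeing the data kept protein-coding genes alone, left out genes whose 3′ UTR holds either of 2 pairs of 7-base words, or kept genes whose control levels at the 2 times were within 4-fold. The words came from a search, also chosen after seeing the data, that ranked 7-base words by how the changes of protein-coding genes with the word in the longest annotated 3′ UTR differed from those of genes without it. Mitochondrially encoded genes at 48 h were not analysed here.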

Results

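The series concerns anillin (ANLN) in the cell nucleus, the clustering of RNA polymerase II at transcription initiation and the expression of genes that depend on it. Its RNA-seq part, described here, asked which transcripts change when ANLN is depleted. KYSE150 cells received an siRNA against ANLN (siANLN) or a control siRNA (siNC), and poly(A) RNA was sequenced after 24 h and 48 h, with 3 libraries in each of the 4 groups. The labels call these libraries biological replicates, and whether they came from separate transfections was not tested. Total gene counts ran from 14891932 to 17921808 per library at 24 h and from 11805488 to 12448411 at 48 h. As far as the labels say, 1 siRNA was used per arm, so the comparison is between those 2 siRNAs.

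ANLN (ENSG00000011426, GRCh38 chromosome 7, 36389806 to 36453791, plus strand) was lower in every siANLN library than in every siNC library at both times. At 24 h its level was 104 ± 6.12 CPM in siANLN against 892 ± 17 CPM in siNC (mean ± SD, n = 3 each), so that 11.6% remained. The log2 change at 24 h was −3.11 (SE 0.04, edgeR Benjamini-Hochberg adjusted p = 1.3e-66). At 48 h the levels were 80.8 ± 5.36 and 731 ± 8.09 CPM, with 11.1% remaining and a log2 change of −3.18 (SE 0.03, edgeR Benjamini-Hochberg adjusted p = 9.2e-274). The 2 changes differed by −0.05 (SE 0.05), which did not pass the test of the difference (edgeR Benjamini-Hochberg adjusted p = 0.59).

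**Figure D1:**
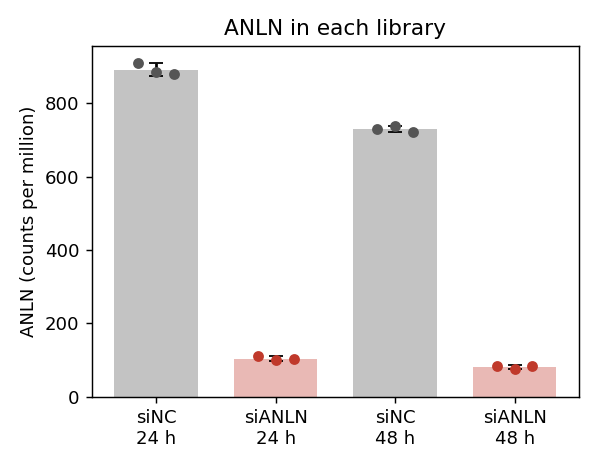
ANLN level (y axis, CPM) in each of the 12 libraries. Points are libraries, bars are group means and error bars are SDs of 3 libraries, and the siANLN libraries lie between 74.6 and 110 CPM and the siNC libraries between 722 and 911 CPM.

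At 24 h the largest rises among protein-coding genes with a mean of at least 5 CPM and no overlap between the groups were those of HABP4, ZNF616, TPM4, MAGEA2B, ZNF138, OGFR, MESD and GANAB. TPM4, a tropomyosin that binds actin filaments, was the most abundant of these and went from 232 ± 3.94 CPM in siNC to 670 ± 11.4 CPM in siANLN, a 2.89-fold rise. GANAB, a subunit of the glucosidase that trims N-glycans in the endoplasmic reticulum, rose 2.25-fold to 526 ± 7.47 CPM, and OGFR rose 2.38-fold to 97.1 ± 2.11 CPM (n = 3 per group). By the same rule the largest falls were those of TMEM64, ERGIC1, C5orf15, CBX2, TAPBPL, WBP1L, AHNAK2 and MARCKSL1. ERGIC1, a protein of the compartment between endoplasmic reticulum and Golgi, went from 157 ± 6.54 to 73.4 ± 1.87 CPM, and CBX2, a Polycomb subunit, from 32.2 ± 2.12 to 17 ± 1.06 CPM.

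In all, 1585 of the 14698 genes tested at 24 h changed (10.8%), 871 of them higher and 714 lower in siANLN. Most changes were small, with a median absolute log2 change of 0.26, and 27 genes rose and 14 fell at least 2-fold. Protein-coding genes made up 847 of the higher and 691 of the lower genes. Among the 16 genes named first, log2 changes ran from 1.17 to 1.61 upward and from −0.79 to −1.36 downward. The weakest of these calls was that of MAGEA2B (log2 1.47, SE 0.23, edgeR Benjamini-Hochberg adjusted p = 6.1e-05). MAGEA2B has a near-identical copy, MAGEA2, so its value is uncertain, and its call was lost in limma-trend on the authors' FPKM (limma Benjamini-Hochberg adjusted p from 0.055 to 0.18 for MAGEA2B at 24 h over 3 settings).

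Several of these genes carry 7-base words that marked rising or falling genes as a class. The annotated 3′ UTRs of TPM4, HABP4, MESD and ZNF616 hold TCGGAGA or CGGAGAA, and that of ZNF616 holds 5 such sites. HABP4 and MESD also hold 1 site each of TTCCCAA or TCCCAAA, and so do, with 1 to 3 sites, the 3′ UTRs of C5orf15, CBX2, WBP1L and MARCKSL1, which fell. These 2 falling words are common: of 11873 genes searched at 24 h, 2105 hold TTCCCAA and 2845 hold TCCCAAA. A falling site in a single gene therefore says little about why that gene changed. The rising words are rarer, with TCGGAGA in 259 genes and CGGAGAA in 308. They were picked by the changes of the genes that hold them, so their presence in top genes does not test a cause. AHNAK2 holds 1 site of the rising pair, OGFR has 7 of them upstream of its 3′ UTR, and GANAB, ZNF138, TMEM64, ERGIC1 and TAPBPL have none of the 4 words in the 3′ UTR. Genes with the 8-base site TCGGAGAA in the 3′ UTR rose at 24 h in 38.0% of 71 cases, against 6.1% of 10769 genes with no site. Genes with TTCCCAAA fell in 16.6% of 920 cases, against 3.5% of 6922 genes with no site. The words were picked in these data by the changes of their genes, so these shares restate that choice. They are not adjusted for 3′ UTR length or GC content. When genes with any of the 4 words in the 3′ UTR were left out, an alternative chosen after seeing the data, 772 genes changed at 24 h. Fewer genes are then tested by construction, and how many is not given here, so 772 cannot be read as a share.

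Among the gene lists at 24 h, 2 of the 24 tested were called, both downward. Of the 10 splits of the 6 libraries into 3 and 3, 5 called at least 2 lists, the real split included. The highest other called 4, so a count of 2 does not stand out from regrouped libraries. Of 15 genes of basal squamous identity, 5 fell (6 adjusted over the list alone), 1 rose and 9 did not pass the test. KRT5, a keratin of basal squamous cells, went from 1990 ± 75.3 to 1500 ± 40.4 CPM (log2 −0.41, SE 0.03), its partner KRT14 changed by −0.34 (SE 0.04), the transcription factor gene BNC1 by −0.39 (SE 0.04) and TRIM29 by −0.19 (SE 0.04). Of the same list, LAMB3, a laminin chain, fell by 0.15 (SE 0.03) and COL17A1, a hemidesmosome collagen, rose by 0.15 (SE 0.03), both named after their values were seen. Of 14 squamous differentiation genes, the keratins KRT17, KRT6A and KRT16 fell, with changes of −0.38, −0.4 and −0.54, and 11 did not pass the test (adjusted over the list alone also 3 fell). The calls of KRT16 and, in the basal list, TRIM29 were among those lost in limma-trend on FPKM with no filter. The median log2 change was −0.09 in the basal list (camera Benjamini-Hochberg adjusted p = 1.9e-04) and −0.06 in the differentiation list (camera Benjamini-Hochberg adjusted p = 0.018). With an estimated correlation neither call held (camera Benjamini-Hochberg adjusted p = 0.33 for both), and without replicate 3 of siNC the differentiation list was not called (camera Benjamini-Hochberg adjusted p = 0.062). KRT14, KRT16, KRT17 and KRT6A have near-identical relatives or pseudogenes, so their values are uncertain, and the 3′ UTRs of KRT5 and BNC1 hold 2 and 1 sites of the falling words.

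The other 22 lists tested at 24 h were not called, with Benjamini-Hochberg adjusted p from 0.079 to 0.95 by camera. Of the transcription machinery, 2 of 12 RNA polymerase II subunit genes rose and 1 fell (2 and 2 adjusted over the list alone), 4 of 61 general transcription factor and Mediator genes rose and 1 fell (4 and 1), and 4 of 26 pausing and elongation factor genes rose and 1 fell (7 and 1). POLR2D, which holds sites of both word pairs in its 3′ UTR, rose by 0.57 (SE 0.05) and POLR2C by 0.25 (SE 0.04). Of the contractile ring genes, 3 of 26 rose and 1 fell (3 and 1), with beta-actin (ACTB) up by 0.31 (SE 0.03). Of G2/M genes 7 of 34 rose and 0 fell (7 and 1), and of S phase genes 4 of 34 rose and 0 fell (6 and 0). The YAP/TAZ and SRF targets had 4 of 22 higher and 2 lower (6 and 3), immediate early genes 3 and 2 of 24 (6 and 5), integrins and focal adhesion genes 3 and 4 of 24 (3 and 6), and mesenchymal genes 2 and 1 of 15 (3 and 2). Epithelial junction genes had 1 higher and 4 lower of 25 (1 and 4), p53 targets 1 and 3 of 24 (1 and 3), interferon-stimulated genes 2 and 2 of 29 (2 and 2) and NF-kB response genes 1 and 2 of 23 (1 and 2). For hypoxia and glycolysis the numbers were 4 and 2 of 30 (5 and 3), for the unfolded protein and ATF4 response 2 and 5 of 29 (4 and 6), for cholesterol synthesis 1 and 2 of 22 (1 and 2), for cytosolic ribosomal proteins 2 and 5 of 69 (2 and 6), for nuclear genes of oxidative phosphorylation 2 and 2 of 39 (2 and 2) and for replication-dependent histones 1 and 0 of 13 (1 and 0). By fry, 4 lists moved on balance in 1 direction at 24 h: both squamous lists downward, and the S phase and pausing lists upward. In the NF-kB, interferon, unfolded protein and mesenchymal lists the median, the mean and the test differed in sign, all within 0.03 of 0.

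At 48 h the largest rises by the same rule were those of INHBA, CXCL8, ZNF616, NOLC1, HABP4, AOX1, TPM4 and GANAB. INHBA, which encodes the activin A subunit, went from 4.87 ± 0.687 CPM in siNC to 33.6 ± 1.15 CPM in siANLN (6.89-fold), and CXCL8, the chemokine interleukin-8, from 6.77 ± 1.02 to 29.2 ± 1.84 CPM (4.31-fold, n = 3 per group). TPM4 (3.2-fold, to 692 ± 10.7 CPM), NOLC1, a nucleolar phosphoprotein (3.24-fold, to 406 ± 9.96 CPM), and GANAB (2.87-fold, to 528 ± 4.93 CPM) were the most abundant of the 8. The largest falls by this rule were those of CYP4F3, TMEM64, MAB21L4, NOTCH3, HAP1, AHNAK2, PLD4 and AQP3. The receptor gene NOTCH3 went from 54.9 ± 1.34 to 13.3 ± 0.633 CPM, TMEM64 from 43.2 ± 1.37 to 9.49 ± 0.517 CPM and AHNAK2 from 312 ± 12.2 to 78.2 ± 1.61 CPM.

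In all, 7402 of 16994 genes tested at 48 h changed (43.6%), 3778 higher and 3624 lower, of which 3169 and 3013 were protein-coding. With scaling by library size alone 42.4% of the changed genes were higher at 48 h, against 51% with TMM. The median log2 change over all genes was −0.039 and −0.003 in these 2 settings, so the split into higher and lower depends on the scaling. Levels are relative to the other genes of a library, so a shift shared by most genes would not show. The median absolute log2 change was 0.3, and 127 genes rose and 293 fell at least 2-fold. Log2 changes of the 16 named genes ran from 1.52 (GANAB, SE 0.03) to 2.79 (INHBA, SE 0.1) and from −1.88 (AQP3, SE 0.17) to −2.56 (CYP4F3, SE 0.18). The weakest of these calls was that of AQP3, a water channel (edgeR Benjamini-Hochberg adjusted p = 6.4e-23). PLD4 overlaps AHNAK2 on the opposite strand and its reads cannot be told apart from those of AHNAK2 without strand, and NOLC1 (rising words) and CYP4F3, HAP1 and NOTCH3 (falling words) each hold 1 site in the 3′ UTR. Of 11922 genes searched at 48 h, 2109 hold TTCCCAA and 2826 hold TCCCAAA, so 1 falling site says little about a single gene. As a class, genes with TCGGAGAA rose at 48 h in 60.0% of 70 cases, against 25.3% of 10815 genes with no site, and genes with TTCCCAAA fell in 38.5% of 901 cases, against 20.7% of 6958. These shares too restate how the words were picked and are not adjusted for 3′ UTR length or GC content.

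The squamous and epithelial junction lists were called downward at 48 h, though some of their genes rose or did not pass the test. Of 15 basal squamous genes 12 fell and 2 rose (12 and 2 adjusted over the list alone), with a median log2 change of −0.42 (camera Benjamini-Hochberg adjusted p = 1.0e-22, 0.012 with an estimated correlation). KRT5 went from 3010 ± 72.5 to 1240 ± 18.4 CPM (log2 −1.28, SE 0.02), KRT14 from 601 ± 18.7 to 269 ± 7.39 CPM, KRT15 from 149 ± 4.77 to 72.8 ± 2.07 CPM and FAT2, a protocadherin, from 882 ± 2.02 to 627 ± 19.4 CPM. COL17A1 and LAMB3 were the 2 that rose, by 0.54 and 0.1. Of 12 squamous differentiation genes 5 fell, 3 rose and 4 did not pass the test (5 and 3 adjusted over the list alone), with a median of −0.34 (camera Benjamini-Hochberg adjusted p = 6.9e-08, 0.04 with an estimated correlation). KRT16 fell by 1.88 (SE 0.08), KRT6A by 1.32 (SE 0.05), KRT17 by 1.28 (SE 0.03) and the protease KLK5 by 0.37 (SE 0.04) on the log2 scale. As at 24 h, the values of KRT14, KRT16, KRT17 and KRT6A are uncertain because of their near-identical relatives or pseudogenes. Of 24 epithelial junction genes 11 fell and 3 rose (12 and 3), with a median of −0.14 (camera Benjamini-Hochberg adjusted p = 1.8e-04, 0.04 with an estimated correlation). The desmosomal genes PKP1 and DSP changed by −0.52 (SE 0.03) and −0.34 (SE 0.02).

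Interferon-stimulated and NF-kB response genes moved in opposite directions at 48 h. Of 26 interferon-stimulated genes 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of −0.35 (camera Benjamini-Hochberg adjusted p = 5.5e-17, 0.012 with an estimated correlation). OASL went from 877 ± 16.2 to 573 ± 14.3 CPM, RSAD2 from 287 ± 5.91 to 195 ± 3.6 CPM, DDX60 from 287 ± 7.76 to 197 ± 5.96 CPM and IFIT3 from 959 ± 11.4 to 741 ± 1.63 CPM. Of 22 NF-kB response genes 18 rose and 1, IL6, fell (19 and 1), with a median of 0.44 (camera Benjamini-Hochberg adjusted p = 5.8e-14, 0.012 with an estimated correlation). The cytokine gene IL1A rose from 80 ± 2.7 to 152 ± 2.54 CPM, and TNFAIP3, a feedback inhibitor of NF-kB, from 61 ± 2.25 to 116 ± 2.68 CPM. IL6 is named because it was the 1 exception, and changed by −0.3. TNFAIP3 holds 1 site of the falling words.

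The hypoxia, cholesterol synthesis and unfolded protein lists were called upward at 48 h, the last not with an estimated correlation. Of 29 hypoxia and glycolysis genes 16 rose and 4 fell (17 and 4 adjusted over the list alone), with a median of 0.14 (camera Benjamini-Hochberg adjusted p = 5.1e-08, 0.017 with an estimated correlation). The glucose transporter gene SLC2A3 rose by 1.21 (SE 0.03), ADM by 0.78 (SE 0.05) and VEGFA by 0.75 (SE 0.05), while CA9, a standard hypoxia marker named after its value was seen, fell by 0.31. Of 21 cholesterol synthesis genes 14 rose and 3 fell (14 and 3), with a median of 0.17 (camera Benjamini-Hochberg adjusted p = 3.6e-05, 0.04 with an estimated correlation). INSIG1 (0.83, SE 0.04) and HMGCS1 (0.48, SE 0.03) were among them, and INSIG1 holds 1 site of the falling words. Of 28 genes of the unfolded protein and ATF4 response 16 rose and 6 fell (17 and 7), among them TRIB3 (from 39.7 ± 1.06 to 89.9 ± 4.95 CPM), DDIT4 (0.76, SE 0.03) and the chaperone gene HSPA5 (0.3, SE 0.02). Its call (median 0.18, camera Benjamini-Hochberg adjusted p = 0.0015) was lost with an estimated correlation (adjusted p = 0.082, Benjamini-Hochberg).

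The contractile ring, RNA polymerase II subunit, pausing, S phase and G2/M lists were also called upward at 48 h, and all of these calls were lost with an estimated correlation. Of 26 contractile ring genes 10 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.05 (camera Benjamini-Hochberg adjusted p = 0.0066, 0.082 with an estimated correlation). The non-muscle myosin gene MYH9 rose from 1790 ± 20.2 to 2680 ± 38.5 CPM and ACTB from 2990 ± 22.6 to 3800 ± 14.7 CPM. Of 12 RNA polymerase II subunit genes 6 rose and 1 fell (7 and 1), with a median of 0.14 (camera Benjamini-Hochberg adjusted p = 0.013, 0.34 with an estimated correlation). POLR2D rose by 0.8 (SE 0.05), POLR2C by 0.52 (SE 0.04), POLR2E by 0.23 (SE 0.03) and POLR2B by 0.18 (SE 0.03); POLR2A, which encodes the largest subunit and is named as the 1 exception, fell by 0.23, but its control level was 715 CPM at 24 h against 36.5 CPM at 48 h, so its 48 h value is uncertain. Of 27 pausing and elongation factor genes 13 rose and 3 fell (15 and 3), among them ELL2 (0.69, SE 0.04) and the NELF subunit gene NELFB (0.4, SE 0.04), with a median of 0.13 (camera Benjamini-Hochberg adjusted p = 0.022, 0.16 with an estimated correlation). Of 33 S phase genes 19 rose and 4 fell (21 and 4), among them RRM2 (0.36, SE 0.03) and MCM7 (0.31, SE 0.03), with a median of 0.15 (camera Benjamini-Hochberg adjusted p = 0.026, 0.099 with an estimated correlation). Of 34 G2/M genes 16 rose and 5 fell (18 and 6), among them BIRC5 (0.84, SE 0.04) and CENPF (0.29, SE 0.02), with a median of 0.07 (camera Benjamini-Hochberg adjusted p = 0.049, 0.3 with an estimated correlation). The G2/M call was also lost without siNC replicate 1, siNC replicate 3 or siANLN replicate 1 of 48 h (camera Benjamini-Hochberg adjusted p = 0.055, 0.052 and 0.088), with scaling by library size alone (median 0.03, adjusted p = 0.13) and with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.058).

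YAP/TAZ and SRF targets had 11 genes higher and 4 lower of 22 at 48 h (11 and 4 adjusted over the list alone), with a median of 0.18 (camera Benjamini-Hochberg adjusted p = 0.018, 0.099 with an estimated correlation). CCN1, a secreted matricellular protein, rose by 0.65 (SE 0.02) and the receptor kinase gene AXL by 0.42 (SE 0.02). Mesenchymal genes went both ways, with 6 higher and 5 lower of 15 (6 and 5) and a median of 0.08 (camera Benjamini-Hochberg adjusted p = 0.0077, 0.082 with an estimated correlation). The mesenchymal call was also lost with no filter (median −0.01, camera Benjamini-Hochberg adjusted p = 0.23) and in the fit on all 12 libraries (median 0, camera Benjamini-Hochberg adjusted p = 0.33), and the median was −0.02 without siNC replicate 1 and −0.03 without siNC replicate 2 of 48 h, so its direction is uncertain. INHBA and THBS1 (0.75, SE 0.02) rose, and COL1A1 (−0.9, SE 0.1) fell. When genes with the 4 words in the 3′ UTR were left out, the S phase, RNA polymerase II subunit and mesenchymal lists were not called (camera Benjamini-Hochberg adjusted p = 0.054, 0.077 and 0.11). Their medians were then 0.14, 0.08 and 0.07, against 0.15, 0.14 and 0.08 with all genes. AXL and RRM2 hold 1, THBS1 3, COL1A1 2 and POLR2D 4 sites of the falling words, and POLR2D also 1 of the rising words.

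The remaining 8 lists tested at 48 h were not called, with Benjamini-Hochberg adjusted p from 0.056 to 0.86 by camera. Replication-dependent histones had 7 genes higher and 0 lower of 11 (7 and 0 adjusted over the list alone, median 0.28), integrins and focal adhesion genes 11 and 5 of 23 (11 and 5), and general transcription factors and Mediator 15 and 7 of 56 (14 and 5). Immediate early genes went both ways, with 9 higher and 8 lower of 23 (9 and 8): FOSL1 rose from 88.6 ± 5.91 to 196 ± 2.81 CPM and FOS fell from 128 ± 1.56 to 57 ± 3.57 CPM. The p53 targets had 8 higher and 7 lower of 23 (8 and 9), with PMAIP1 up by 0.5 (SE 0.03) and the cell cycle inhibitor gene CDKN1A down (−0.79, SE 0.04). Cytosolic ribosomal protein genes had 14 higher and 12 lower of 64 (12 and 12), with a median of 0, a mean of 0.01 and a downward sign in camera, and nuclear genes of oxidative phosphorylation 5 and 4 of 34 (5 and 4). By fry, 19 lists moved on balance in 1 direction at 48 h.

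**Figure D2:**
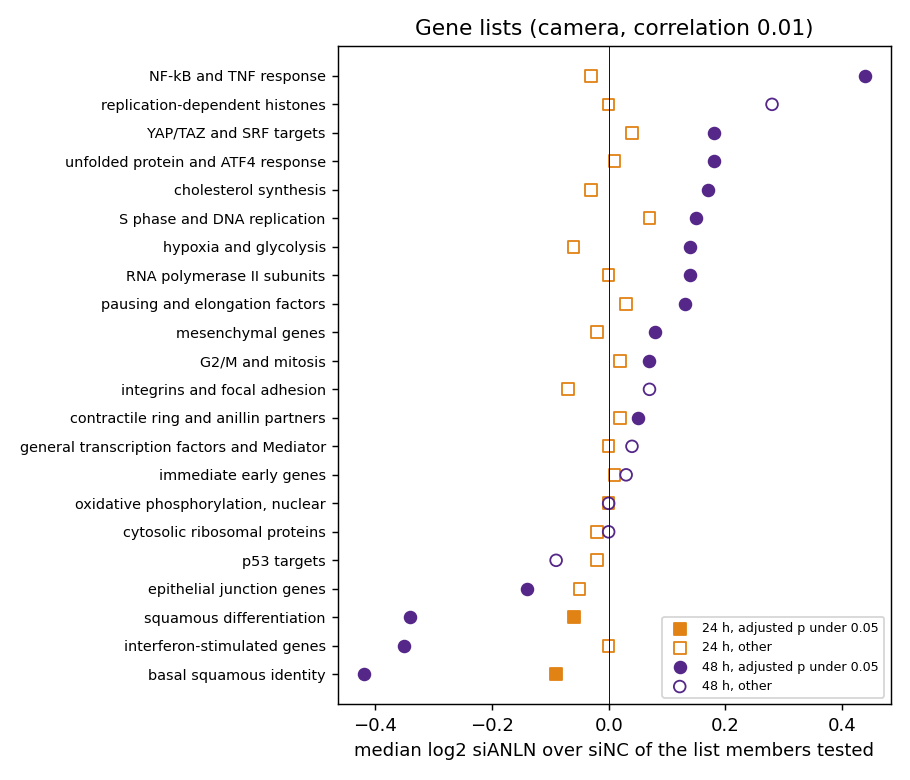
Median log2 change of the tested members of 22 gene lists at 24 h (squares) and 48 h (circles), filled where camera with a correlation of 0.01 gave a Benjamini-Hochberg adjusted p under 0.05. Most 24 h medians lie near 0, while at 48 h basal squamous identity (−0.42) and NF-kB response (0.44) lie at the ends; lists of other cell types and mitochondrially encoded genes are not drawn.

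Few markers of other cell types passed the count filter. Among fibroblast, lymphoid or myeloid and endothelial markers, the highest means at 24 h were those of COL1A1 (5.53 CPM), CSF1R (3.46 CPM) and ERG (1.05 CPM). At 48 h they were those of COL1A1 (14.8 CPM), CD68 (50.9 CPM) and VWF (1.08 CPM). At 24 h the 1 fibroblast, 2 lymphoid or myeloid and 1 endothelial genes tested did not pass edgeR's test, nor adjusted over the list alone (unadjusted p = 0.14 for COL1A1, 0.092 for CSF1R and 0.25 for ERG). At 48 h COL1A1, CSF1R (−0.82) and VWF (−1.43) fell and CD68 (0.73, SE 0.06) rose, the same numbers as adjusted over the list alone, and the pair of lymphoid or myeloid genes was not called as a list (camera Benjamini-Hochberg adjusted p = 0.86 at 24 h and 0.37 at 48 h). CD68 overlaps 2 other genes and its control level, on the separate scaling used to compare the times, was 0.0649 CPM at 24 h against 39.5 CPM at 48 h, so it is uncertain. Mitochondrially encoded genes took 3.42% to 3.59% of the 24 h counts. Of 13 tested at 24 h 1 passed (1 adjusted over the list alone), MT-ND5 (0.14, SE 0.04, edgeR Benjamini-Hochberg adjusted p = 0.029), whose call was lost in the DESeq2 Wald test, limma-voom and limma-trend on FPKM and without any of 3 single libraries (siNC replicates 1 and 2, siANLN replicate 1).

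Most genes changed at 24 h changed in the same direction at 48 h. Of 845 genes higher at 24 h among the 13184 genes in both fits, 744 (88%) were also higher at 48 h, where independent lists would share 208.9 (odds ratio 28.8). Of 688 lower at 24 h, 550 (79.9%) were also lower at 48 h, where independent lists would share 159.2 (odds ratio 15.9). In opposite directions 26 genes changed, against 365.6 under independence. HABP4, ZNF616, TPM4 and GANAB were among the 8 rises named at both times, and TMEM64 and AHNAK2 among the 8 falls. Across the 13184 genes, which are not independent replicates, the log2 changes of the 2 times had a Pearson r of 0.46 and a Spearman rho of 0.47, and over the 1532 genes changed at 24 h, ANLN left out, Pearson r was 0.85. Of the 1294 genes changed in 1 direction at both times 81.5% changed more at 48 h, with a median ratio of 1.49. Without genes that hold the 4 words in the 3′ UTR, 623 were shared, out of fewer genes tested by construction. The 2 times have separate controls, so the overlap holds no shared control error, but they share the siRNAs.

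**Figure D3:**
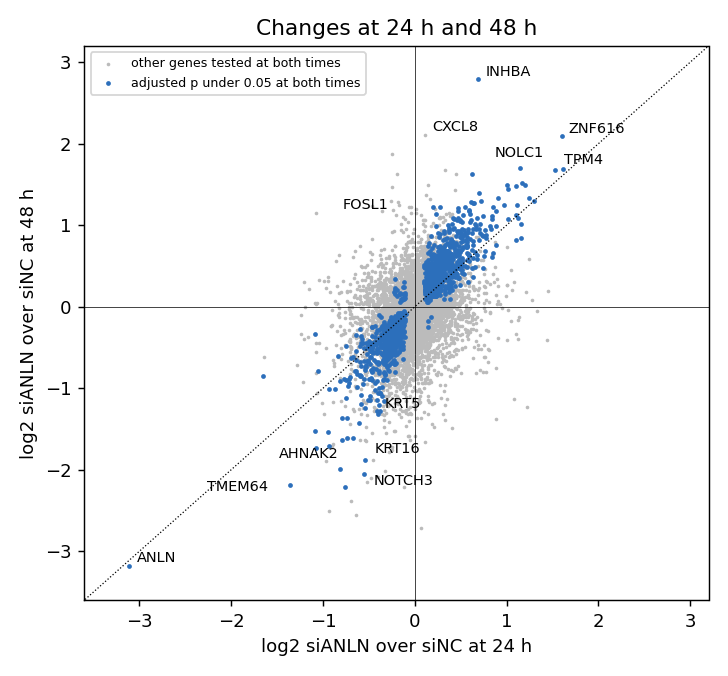
Log2 change, siANLN over siNC, of the 13184 genes tested at both times, at 24 h (x axis) and 48 h (y axis), with genes past the threshold at both times in blue and equal changes on the dotted line. ANLN lies at −3.11 and −3.18, and INHBA and CXCL8 lie far above the line.

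The change differed between the times for 2292 of 17625 genes tested, 1461 of them more positive and 831 more negative at 48 h. The 8 genes with the smallest p were KRT5, FOSL1, AHNAK2, NEDD4L, KRT17, PHLDA1, PPIF and KRT14. FOSL1, a subunit of the AP-1 transcription factor, did not pass the test at 24 h (−0.04, SE 0.04). At 48 h it lay 1.15 (SE 0.04) higher in siANLN than in siNC, a difference of 1.2 (SE 0.05, edgeR Benjamini-Hochberg adjusted p = 1.4e-32). In siNC it was 259 ± 7.5 CPM at 24 h and 88.6 ± 5.91 CPM at 48 h, against 252 ± 7.57 and 196 ± 2.81 CPM in siANLN. Its siANLN level was thus not higher at 48 h than at 24 h, while its control level was lower. Levels of the 2 times also carry the different processing of the tables. NEDD4L, a ubiquitin ligase gene, changed by 1.05 more at 48 h, PHLDA1 by 0.93 and the mitochondrial cyclophilin gene PPIF by 0.77. KRT5 changed by −0.85 (SE 0.04), KRT17 by −0.89, KRT14 by −0.8 and AHNAK2 by −1.17 more in the negative direction. The 3′ UTR of PHLDA1 holds 2 sites of the falling words, and FOSL1, NEDD4L and PPIF hold none of the 4 words there.

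Of 24 lists tested for the difference 16 were called, 12 toward higher and 4 toward lower values at 48 h, and 9 of these with an estimated correlation. Of the called lists, the NF-kB list shifted most (median difference 0.55, 16 of 22 genes more positive, 18 adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 1.3e-19, 1.7e-04 with an estimated correlation). The histone list followed (median 0.42, camera Benjamini-Hochberg adjusted p = 0.0043, 0.043 with an estimated correlation). Of its 20 genes 13 were tested, of which 3 were more positive (5 adjusted over the list alone) and 10 did not pass the test. The called list with the largest negative shift was the interferon list (median −0.32, 18 of 26 genes more negative, 21 adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 1.5e-22, 0.0018 with an estimated correlation). The basal squamous list differed by a median of −0.23, with 7 of 15 genes more negative and 2 more positive (8 and 2 adjusted over the list alone, camera Benjamini-Hochberg adjusted p = 5.1e-09, 0.0099 with an estimated correlation). The p53 and immediate early lists, which were not called, had medians of −0.06 and −0.01 and an upward sign in camera. The tables of the 2 times were processed differently and time is confounded with that. Differences of genes whose control level also differs widely are therefore uncertain. Examples, 24 h against 48 h in siNC, are FOS (16.6 against 131 CPM), CYP4F3 (2.4 against 10.7 CPM), PLD4 (0.233 against 14.5 CPM) and PRC1 (1.98 against 119 CPM). Others are NOTCH3 (16.3 against 56.2 CPM), KRT15 (45.1 against 152 CPM), HAP1 (3.43 against 9.41 CPM), AQP3 (2.66 against 9.19 CPM) and FOSL1 (269 against 90.7 CPM). These control levels are on the separate scaling used to compare the times. The library strand is not given in the sources used here, so reads cannot be told apart between named genes and the genes that overlap them, among them ANLN (MATCAP2), TMEM64 (NECAB1), OGFR (OGFR-AS1), INHBA (INHBA-AS1), MESD (CEMIP), TAPBPL (VAMP1 and CD27), HABP4 (CDC14B), RSAD2 (CMPK2), IFIT3 (LIPA), MCM7 (AP4M1) and THBS1 (THBS1-AS1), whose values are uncertain to that extent.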

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

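Chosen only after the result was seen were the tests of the 8-base sites and those of depth and of larger changes at 48 h, as was leaving out genes with the words.

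The change between siANLN and siNC differed between 24 h and 48 h for 2292 genes, and each gene and list below was picked out by that test (edgeR for genes, camera for lists). Of genes named for their rise at 24 h or 48 h, the change at 48 h minus that at 24 h was 2.11 for INHBA, 2.01 for CXCL8, 1.36 for AOX1, 0.56 for NOLC1, 0.37 for GANAB, 0.32 for MESD and 0.16 for TPM4 on the log2 scale. Of those named for their fall it was −1.9 for CYP4F3, −1.68 for HAP1, −1.62 for MAB21L4, −1.48 for NOTCH3, −1.42 for AQP3, −1.17 for AHNAK2, −0.84 for MARCKSL1, −0.81 for TMEM64, −0.77 for TAPBPL, −0.57 for C5orf15 and −0.41 for ERGIC1. For other genes among the 8 with the smallest p of the difference it was 1.2 for FOSL1, 1.05 for NEDD4L, 0.93 for PHLDA1 and 0.77 for PPIF.

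Squamous and junction genes differed by −0.85 (KRT5), −0.8 (KRT14), −1.08 (KRT15), −0.89 (KRT17), −1.33 (KRT16), −0.9 (KRT6A), −0.47 (FAT2), −0.37 (TRIM29), −0.33 (KLK5), −0.38 (PKP1) and −0.32 (DSP), and by 0.4 (COL17A1) and 0.27 (LAMB3) in the other direction. The median difference was −0.23 in the basal squamous list, −0.19 in the squamous differentiation list and −0.08 in the junction list. Interferon-stimulated genes differed by −0.52 (OASL), −0.48 (DDX60), −0.33 (IFIT3) and −0.22 (RSAD2), with a list median of −0.32. IL1A and TNFAIP3 each differed by 0.84, with a median of 0.55 in the NF-kB list.

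Of the hypoxia list (median 0.17), SLC2A3 differed by 0.76, VEGFA by 0.69 and ADM by 0.64. Of the cholesterol list (0.22), INSIG1 differed by 0.78 and HMGCS1 by 0.49, and of the unfolded protein list (0.21), TRIB3 by 0.72, DDIT4 by 0.56 and HSPA5 by 0.32. The median difference was 0.42 in the histone list. These calls held with an estimated correlation, as did those of the squamous, junction, interferon and NF-kB lists.

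The calls of 7 other lists were lost with an estimated correlation. Their median differences were 0.04 in the contractile ring list (adjusted p = 0.061 with an estimated correlation, camera), 0.09 in the G2/M list (adjusted p = 0.28 with an estimated correlation, camera), 0.14 in the RNA polymerase II subunit list (adjusted p = 0.16 with an estimated correlation, camera) and 0.11 in the pausing list (adjusted p = 0.054 with an estimated correlation, camera). They were 0.14 in the YAP/TAZ and SRF list (adjusted p = 0.15 with an estimated correlation, camera), 0.12 in the integrin list (adjusted p = 0.096 with an estimated correlation, camera) and 0.12 in the mesenchymal list (adjusted p = 0.084 with an estimated correlation, camera). Of their genes, MYH9 differed by 0.45, PRC1 by 0.67, BIRC5 by 0.5, POLR2B by 0.16, POLR2C by 0.29, POLR2D by 0.24, POLR2E by 0.26, ELL2 by 0.64, NELFB by 0.22, CCN1 by 0.3, AXL by 0.41, THBS1 by 0.61 and COL1A1 by −0.64. Of lists not called, MCM7 differed by 0.29, RRM2 by 0.27, FOS by −1.21, CDKN1A by −0.39 and PMAIP1 by 0.24.

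For the number of genes whose change differed, 5 of 100 splits of the libraries within each time gave at least 2292 genes, the real one included, and the highest other gave 5340. All 5 kept the real groups of 48 h, 4 of them mirrored, so the change at 48 h entered these counts by construction and they do not decide about chance. The highest count among the 89 splits that did not keep those groups was 1. For the 1294 genes changed in 1 direction at both times, 1 of 100 splits, the real one, gave as many, and the highest other, which kept both real groupings mirrored, gave 26. Other groupings call almost no genes at either time, so few or no shared genes follow from that. The splits therefore do not test whether the overlap is larger than separate effects at the 2 times would give. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At 24 h the real split gave 1585 genes and the highest other 1, and at 48 h 7402 and 0. For lists, the real split gave 2 at 24 h and the highest other 4 (5 splits had at least 2), and at 48 h 15 and 4 (1 split had at least 15). The number of lists called at 24 h thus did not stand out from other groupings.

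More genes changed at 48 h than at 24 h, by a ratio of 4.67. A smaller replicate spread at 48 h was not the whole cause: with 1 spread shared by all 12 libraries the counts were 2026 and 6103, a ratio of 3.01. Depth goes the other way, with a mean total at 48 h that was 0.75 times that at 24 h. Larger changes at 48 h may account for part of it, since the median ratio of the 48 h to the 24 h change was 1.36 over 1532 genes changed at 24 h, and 69.3% of these had a ratio over 1. Time cannot be separated from the different processing of the tables, which keeps a biological reading of the growth with time open.

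Genes with TCGGAGA or CGGAGAA in the 3′ UTR lay higher in siANLN, and these words ranked 1 and 2 of 16221 words at 24 h and 1 and 4 of 16236 at 48 h. Genes with the 8-base site TCGGAGAA, which joins both words, lay 0.344 (SE 0.043) higher at 48 h, adjusted for 3′ UTR length and GC content. The reverse complement, which has the same GC content, gave 0.038 (SE 0.043), which argues against GC content alone. It does not test a high share of A and G on 1 strand, and the site, unlike it, was picked for its effect. Words that share GGAGAA with the site also ranked high at 48 h (GGAGAAA 2, TGGAGAA 3 and AGGAGAA 5). Off-target silencing by the control siRNA, relieved in siANLN, stays open, since the words were picked because their genes lay highest in these data and the size of the site's effect restates that. The site upstream of the 3′ UTR gave 0.126 (SE 0.02), which does not decide either, as the words were picked in 3′ UTRs. The sequence of the control siRNA is not given in the sources used here, and a response to ANLN loss through the same genes stays open too.

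Genes with TTCCCAA or TCCCAAA in the 3′ UTR lay lower in siANLN, and these words ranked 1 and 2 at both times. The 8-base site TTCCCAAA gave −0.101 (SE 0.013) at 48 h and −0.074 (SE 0.008) at 24 h, while its reverse complement gave −0.013 (SE 0.012) at 48 h, which argues against GC content alone. The reverse complement does not test the base composition of 1 strand, and the site, unlike it, was picked for its effect. Off-target silencing by the ANLN siRNA stays open, since the words were picked in these data and the effect upstream of the 3′ UTR, −0.074 (SE 0.016) at 48 h, was not clearly weaker. It cannot be told apart from another cause tied to the word. The ANLN mRNA holds TTCCCAAA in coding exon 4 (GRCh38 chromosome 7, 36406473 to 36406480, plus strand), and the sequence of the ANLN siRNA is not given in the sources used here.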

How the results depend on the processing

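Protein-coding genes alone, genes without the 7-base words and genes with control levels within 4-fold were alternatives chosen only after the result was seen; the others were planned.

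No called result was called in the other direction in an alternative, but the median of the mesenchymal list at 48 h (0.08) was −0.01 with no filter, 0 in the fit on all 12 libraries, and −0.02 and −0.03 without siNC replicates 1 and 2. ANLN stayed between −3.04 and −3.21 on the log2 scale in every alternative run. The 1585 genes changed at 24 h became 761, 778 and 349 in limma-trend on FPKM (log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) with no filter), 1055 at an adjusted p under 0.01, 41 at 2-fold or more and 772 without genes holding the words. The 7402 of 48 h became 4232 on FPKM with no filter and 420 at 2-fold or more. The 2292 that differed became 1415 at the stricter p and 170 at 2-fold or more, and the 1294 shared became 20 at 2-fold or more and 623 without the words. Leaving out genes with the words tests fewer genes by construction; the cause of the other changes was not tested. Lists called at 24 h (2) became 4 with all 12 libraries in 1 fit, 0 by camera with an estimated correlation (3 at an unadjusted p under 0.05), 4 by fry and 6 without the words, and lists called at 48 h (15) became 7 with an estimated correlation. Leaving out 1 library gave 1285 to 1421 genes at 24 h, 6631 to 6809 at 48 h, 1884 to 2310 that differed, 1078 to 1273 shared, 1 to 3 lists at 24 h and 14 to 16 at 48 h. The 1 list came from leaving out siNC replicate 3 of 24 h.

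The replicate number as a block gave 1772 genes at 24 h, 7355 at 48 h, 2392 that differed and 1403 shared, with 3 lists at 24 h (S phase added, camera Benjamini-Hochberg adjusted p = 0.032) and 15 at 48 h. Same-numbered libraries correlated by 0.05, 0.08 and −0.07 at 24 h and −0.01, −0.03 and 0.04 at 48 h, so the numbers were not taken as pairs. Of named genes at 24 h, 14, 13 and 24 lost their call in the 3 FPKM tests, 2 in the DESeq2 Wald test, 1 in limma-voom and 9 of 437 values on leaving out 1 library. At 48 h 3 did, on FPKM with no filter. On FPKM with no filter these included TRIM29 at 24 h (limma Benjamini-Hochberg adjusted p = 0.12), KRT16 at 24 h (0.14), POLR2B at 48 h (0.074) and VWF at 48 h (0.26). With library size alone 42.4% of genes changed at 48 h were higher, against 51%. On simulated data at the real depths, 30 of 50 genes changed by the smallest fold tried were called at 24 h, 28 at 48 h and 13 for the difference, so small changes can be missed.

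Some lists not called at 24 h were called in alternatives (camera Benjamini-Hochberg adjusted p). The S phase list was called with no filter (0.018), in the fit on all 12 libraries (0.019) and without siNC replicate 2 or siANLN replicate 3 (0.036 and 0.03). The ribosomal protein list was called in the fit on all 12 libraries (0.045), without siNC replicate 1 or siANLN replicate 2 (0.031 and 0.015) and without the words (0.031), as were the pausing, YAP/TAZ and integrin lists without the words (0.031, 0.036 and 0.043). At 48 h the histone list was called with library size alone (0.047), with no filter (0.0014), in the fit on all 12 libraries (0.013) and without siNC replicate 2 (0.038). The integrin list was called with no filter (0.0097) and without the words (0.038), and the general transcription factor list with no filter (0.019).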

Other observations

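The zinc finger comparison, with its version without the 7-base words, was chosen only after the result was seen.

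Of 356 protein-coding genes with symbols starting in ZNF, a family of zinc finger proteins, 72 were higher and 7 lower in siANLN at 24 h, with a median log2 change of 0.11 against −0.01 in other coding genes. At 48 h 137 were higher and 47 lower, with medians of 0.15 and −0.01. With scaling by library size alone 125 were higher and 56 lower at 48 h, with medians of 0.11 and −0.04, and with DESeq2 size factors the numbers of both times were those of TMM. Without genes that hold the 4 words in the 3′ UTR, 41 of 213 were higher and 3 lower at 24 h, and 88 of 217 were higher and 26 lower at 48 h. Genes with the words only upstream of the 3′ UTR stayed in. The family was not tested as a list.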
